A study of Homo sapiens with 6 samples.

How the data were processed

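GIST-T1 cells were measured untreated, after 5-aza-dC and after 5-aza-dC followed by 4-PBA, with 2 arrays per group. Per the labels' protocols, drug and medium were renewed every 24 h, and 100 ng of total RNA was labelled with Cy3. Each file is the scanner output of 1 Agilent array with 62976 spots, of which 58717 were not controls and held 50599 probes. Per the file headers, the processed signal is an intensity that Agilent Feature Extraction had background-subtracted and spatially detrended, with values near background replaced by a small surrogate and no scaling between arrays. The version was 10.7 per the submitters' processing notes. The values in the series table were the same intensities, as deposited by the authors, not logged, centred or scaled, rounded to 3 digits (ratio to the scanner value between 0.995 and 1.005). Their medians were 11.4 and 9.6 on the untreated arrays, 8.33 and 11.2 after 5-aza-dC, and 9.42 and 12.1 after the combined treatment. All arrays lie on 1 slide and come from 1 scan, so no batch could be tested. The arrays of the combined treatment stand in 1 row of the slide and the others in another, so slide row and combined treatment cannot be told apart.

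The log2 of the processed signal was taken, less the 75th percentile of each array. Since under 0.5 of the probes were detected, that percentile was taken over the 20926 spots well above background on all arrays. Control spots and spots marked as outliers were left out, which dropped 30 probes, spots of a probe were averaged, and each gene was represented by its probe with the highest mean. Well above background were 45.0 and 42.5% of the spots on the untreated arrays, 38.7 and 38.8% after 5-aza-dC, and 42.7 and 44.1% after the combined treatment. No spot was saturated, and the number of arrays limits the precision. Gene names came from the files, and 28174 probes were matched through a RefSeq accession to a table of assembly GRCh38.p14, used for names only, which renamed 4387. Of the probes, 30349 had an official symbol. Of 3622 genes with several tested probes, 125, 31 and 50 had probes called both ways in the 3 comparisons (5-aza-dC, combined treatment, and between them). Probe coordinates are those of the files, on hg19. Exon and UTR annotation was not used here. A gene was tested where it was well above background on every array of at least 1 group: 15632 of 36603 genes, which leaves 20971 too dim to test. A gene dim in untreated cells thus enters only by being bright after a treatment, which favours rises in lists of silent genes.

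Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of all 6 arrays, with 3 residual and 1.84 prior degrees of freedom, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The median standard error was 0.116 on the log2 scale, and replicates correlated across genes with r = 0.984 (untreated), 0.990 (5-aza-dC) and 0.993 (combined). Where a gene was not well above background on any array of a group, its change is given as at least N-fold, the mean of the brighter group against the mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. Lists were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, over 29 gene lists: cancer-testis antigens, germline genes silenced by promoter methylation, interferon-stimulated genes, nucleic-acid sensors and their adaptors, interferons, chemokines and inflammatory cytokines, MHC class I antigen presentation, MHC class II antigen presentation, immune checkpoint and NK ligands, endogenous retroviral envelope and related genes, p53 target genes, G2/M and mitosis genes, DNA replication and S-phase genes, GIST and interstitial-cell-of-Cajal lineage genes, MAPK and PI3K pathway output genes, replication-independent and polyadenylated histone genes, tumour-suppressor and silenced-in-cancer genes, imprinted genes, DNA methylation and histone deacetylation machinery, neuronal genes, ER stress and unfolded protein response genes, cholesterol and fatty acid synthesis genes, fatty acid oxidation and PPAR target genes, metallothioneins and oxidative stress genes, smooth muscle genes, epithelial genes, leukocyte genes, Schwann and melanocyte genes, fibroblast and endothelial genes and homeobox genes. The lists, the tests and the rule for named genes were fixed before the data were examined. In each comparison that rule names, among genes with an official symbol, the 4 largest rises and 4 largest falls among called genes well above background on every array of both groups, and up to 4 called genes dim on all arrays of a group, by adjusted p. It adds the called members of each list with the largest change (2 for lists of the main themes, 1 for others), members needed to say what a list's change consists of, and always KIT, DNMT1, DNMT3A, DNMT3B, HDAC1, HDAC2 and CDKN1A. CDKN1A was too dim to test, and the rule lets list members be left out for space. Plots were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the lists and genes in the plots were picked from these after their values were seen.

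The fit was tested on simulated data with the means and moderated spreads of the 15632 genes, with 50 genes changed at each of 1.5-, 2-, 4- and 8-fold. For 5-aza-dC against untreated it recovered 2, 38, 43 and 50 of 50 with 11 false calls, for the combined treatment against untreated 9, 35, 47 and 48 with 10, and for the combined treatment against 5-aza-dC 5, 32, 46 and 48 with 6. Far more genes were called in the data (7628, 6002 and 6615) than were changed here, which loosens the Benjamini-Hochberg cut. These recovered and false calls therefore do not carry over to the data. In each simulation, a changed list was called and 0 of 100 unchanged lists were. Genes were simulated independently of each other, and all genes of the changed list rose at least 2-fold. The simulation therefore says nothing of camera on lists whose genes are correlated. The alternatives set with the design were normexp (offset 50) with quantile normalization, quantile normalization, median centring, the series table's values, no filter on dim probes, genes above background on all arrays, an intensity trend, robust eBayes, fits of only the 4 arrays compared, a replicate block, the mean of a gene's probes, each probe alone, a 2-fold minimum, an estimated correlation, and leaving out each array. Chosen after seeing the data were the 75th percentile over all non-control probes, spike-in scaling, no scaling, and leaving out the spots of a dim patch on untreated replicate 2.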

Results

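GIST-T1 is an established human cell line from a gastrointestinal stromal tumour, a tumour of the gut wall that usually depends on the receptor tyrosine kinase KIT. Messenger RNA of these cells was measured on Agilent 1-colour arrays after treatment with drugs that relieve epigenetic silencing. 5-aza-2'-deoxycytidine (5-aza-dC) is a cytidine analogue that is built into DNA and traps DNA methyltransferases, and 4-phenylbutyric acid (4-PBA) inhibits histone deacetylases. The 6 arrays formed 3 groups of 2: untreated cells, cells given 5-aza-dC at 2 µM for 72 h, and cells given the same course of 5-aza-dC and then 4-PBA at 3 mM for 48 h. No group received 4-PBA alone. Between 38.7% and 45.0% of spots were well above background on each array, with the lowest shares, 38.7% and 38.8%, on the 5-aza-dC arrays. In each comparison 15632 genes were tested. Changes are differences of group means on the log2 scale, ± the standard error of the limma fit (n = 2 arrays per group), and each adjusted p is limma's with Benjamini-Hochberg adjustment unless camera is named. A gene not well above background on any array of a group is given as a least fold. For all 44, 44 and 38 called genes named in the 3 comparisons, the arrays of the groups compared did not overlap. Unselected genes would do so by chance in 33.3% of cases, but these genes were chosen as called on the same arrays, so this adds no evidence. Where members of a fixed list are counted, the count adjusted over the list alone is given if it differs. A list is said to pass by camera, which compares it with other genes. Fry, which compares it with no other genes, passed 23, 27 and 25 of the 29 lists in the 3 comparisons as moving 1 way, and 29 in each as changing either way. The labels do not make plain whether the untreated and 5-aza-dC cells were kept for the further 48 h of the combined treatment, so a difference in culture time between the groups is not excluded in any comparison. The number of arrays limits the precision, and no label says that the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

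The first comparison set cells given 5-aza-dC alone against untreated cells. Genes of cell division were lower: 50 of 52 genes of G2/M and mitosis fell, with a median change of -1.86, and 52 of 53 genes of DNA replication and S phase fell, with a median of -1.66. Both lists passed camera with a preset correlation (adjusted p = 4.44e-24 and 5.04e-23) and with an estimated one (adjusted p = 0.0474 and 0.0452). RRM2, the small subunit of ribonucleotide reductase (chromosome 2, 10270487 to 10270546 in hg19), fell by 3.35 ± 0.13 (10.2-fold lower, adjusted p = 0.000419). TOP2A, topoisomerase II alpha, was at least 9.22-fold lower (adjusted p = 0.000481). CENPA, the centromeric histone H3 variant, fell by 3.19 ± 0.17, with 1 of the 2 5-aza-dC arrays well above background. POLE2, a subunit of DNA polymerase epsilon, was at least 2.36-fold lower, a call lost without untreated replicate 2 (adjusted p = 0.0501). The 5-aza-dC arrays, which carried these lower cell division genes, also had less gene signal against the spike-in RNA than the untreated arrays, by 1.06 on the log2 scale. The scaling of each array on its own gene signal removes that shift, so every change given here is relative to the gene signal of the array. Scaled on the spike-ins instead, the median change of all genes was -0.99, and 3.88% of the called genes were higher, against 55.2%. Unscaled arrays gave a median of -0.77 and 5.47% higher.

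**Figure D1:**
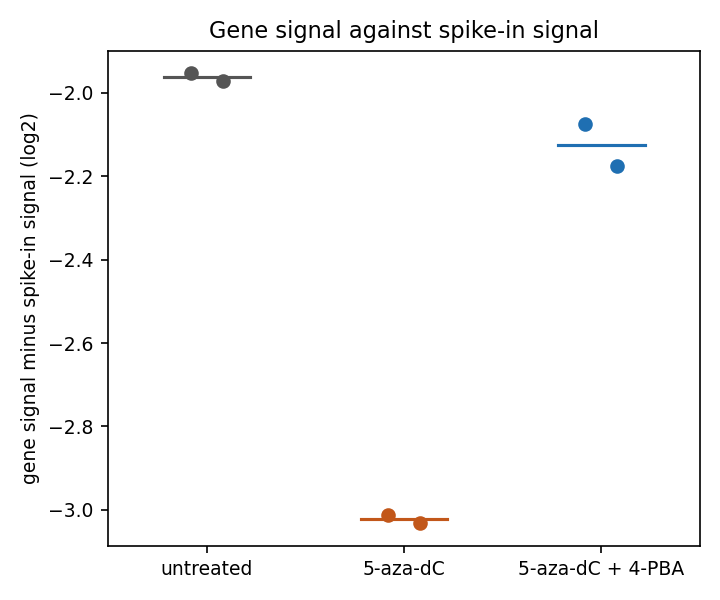
The 75th percentile of the log2 gene signal minus the mean log2 spike-in signal (vertical axis) on each of the 6 arrays, by group (horizontal axis). The 5-aza-dC arrays lie at -3.01 and -3.03, the untreated arrays at -1.95 and -1.97, and the arrays of the combined treatment at -2.07 and -2.18.

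In all, 7628 of 15632 genes changed after 5-aza-dC, 4207 higher and 3421 lower, and 2444 changed at least 2-fold. Among named genes measured on every array, the largest rises were those of SULF2, an extracellular sulfatase, by 4.00 ± 0.51, and MMP1, interstitial collagenase (chromosome 11, 102660697 to 102660756), by 3.99 ± 0.07 (15.8-fold). RGS16, a regulator of G-protein signalling, rose by 3.73 ± 0.28 and EPAS1, a hypoxia-inducible factor, by 3.60 ± 0.12. The untreated arrays differed for SULF2, at -2.27 and -3.83. MMP10, stromelysin 2, was at least 18.7-fold higher (adjusted p = 0.000342) and SYT7, a synaptotagmin, at least 71.0-fold higher (adjusted p = 0.000342). The largest falls were those of the small NF90-associated RNAs SNAR-B2, by 3.44 ± 0.12, SNAR-G2, by 3.40 ± 0.13, and SNAR-A3, by 3.37 ± 0.09, and of the histone H2A gene H2AC13, by 3.43 ± 0.18. SNAR genes are near-identical copies, so which copy fell is uncertain. AJAP1, an adherens junction protein, was at least 2.42-fold lower (adjusted p = 0.000397).

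Of the 46 genes of the DNA methylation and histone deacetylation machinery tested, 10 rose and 13 fell (camera, adjusted p = 0.425). DNMT1, the maintenance DNA methyltransferase, fell by 1.16 ± 0.13 (adjusted p = 0.00277), and UHRF1, which brings DNMT1 to newly replicated DNA, fell by 2.17 ± 0.07. DNMT3B (-0.13 ± 0.14), HDAC1 (-0.08 ± 0.09) and HDAC2 (-0.12 ± 0.10) did not pass the test, and passed as lower with spike-in scaling (-1.19, -1.14 and -1.18). DNMT3A was 0.34 ± 0.09 (adjusted p = 0.0287) on its brightest probe and -0.31 and -0.03 on the others. Its call was lost with the mean of its probes (0.00, adjusted p = 0.972), without each array other than untreated replicate 1, and in several other settings. KIT (chromosome 4, 55606511 to 55606570 in hg19) fell by 1.46 ± 0.08 (2.76-fold lower, adjusted p = 0.000591), and its other probes gave -1.01 and -1.18. Of the 31 genes of the GIST and interstitial-cell-of-Cajal lineage tested, 7 rose and 15 fell (camera, adjusted p = 0.0757). That list passed without untreated replicate 2 (adjusted p = 0.0381), with the mean of each gene's probes (adjusted p = 0.0269), with every probe on its own (adjusted p = 0.0285) and without the filter on dim probes (adjusted p = 2.2e-05). PRKCQ, protein kinase C theta, fell by 1.58 ± 0.16, with 1 of the 2 5-aza-dC arrays well above background, and SCG2, secretogranin II, rose by 1.57 ± 0.29. CDKN1A was not well above background on any array and was not tested.

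Of the 25 listed histone genes tested, 0 rose and 17 fell (0 and 18 adjusted over the list alone, camera, adjusted p = 8.76e-07, and adjusted p = 0.332 with an estimated correlation). H2AC20 fell by 1.81 ± 0.10 and H2BC7 was at least 1.43-fold lower. Both belong to the histone gene clusters, most of whose genes are transcribed during DNA replication. The list, named for replication-independent and polyadenylated histone genes, thus also holds genes of those clusters. Of the 25 metallothioneins and oxidative stress genes tested, 15 rose and 3 fell (camera, adjusted p = 0.0155, and adjusted p = 0.631 with an estimated correlation). The median of that list, 0.77, was -0.29 with spike-in scaling and -0.064 unscaled. Without the filter on dim probes it lost its call (adjusted p = 0.207), and the 9 lists that passed there were all lower than other genes, those of lineage, methylation machinery, MAPK and PI3K output, ER stress, homeobox and cholesterol genes among them. Of the genes called without that filter, 10650 were higher and 2556 lower, so a list lower than other genes there need not have fallen. MT1L, one of several near-identical metallothionein copies, rose by 2.49 ± 0.09. No other list passed camera after 5-aza-dC alone in the main setting. With spike-in scaling the cancer-testis (adjusted p = 0.000468), fibroblast and endothelial (adjusted p = 0.0138) and checkpoint lists (adjusted p = 0.00754) passed as higher than other genes, with medians of -0.52, 0.0084 and -0.70, as did the first 2 unscaled (adjusted p = 0.00161 and 0.0327). Of the 43 p53 target genes tested, 20 rose and 7 fell (camera, adjusted p = 0.315). GDF15, a secreted stress cytokine, rose by 3.12 ± 0.08 (8.68-fold). Of the 59 interferon-stimulated genes tested, 22 rose and 12 fell (camera, adjusted p = 0.339). With spike-in scaling 4 of them rose and 38 fell, with a median of -0.82 against -0.99 for all genes. Unscaled, 4 rose and 27 fell, with a median of -0.59 against -0.77. USP18, which removes the ubiquitin-like ISG15 from proteins, was at least 2.57-fold lower (adjusted p = 0.000342). Of the 16 nucleic-acid sensors and adaptors tested, 6 rose and 1 fell (camera, adjusted p = 0.237), and the list passed without untreated replicate 2 (adjusted p = 0.041) and with every probe on its own (adjusted p = 0.0177). STING1 rose by 1.38 ± 0.07, and RIGI was 1.22 ± 0.16 on its brightest probe but 0.21 as the mean of its probes (adjusted p = 0.334). Of the 20 genes of MHC class I antigen presentation tested, 10 rose and 2 fell (camera, adjusted p = 0.169). TAPBP, tapasin, rose by 1.12 ± 0.07. HLA-C was 1.87 ± 0.48 (adjusted p = 0.0287), from a probe in a dim patch of untreated replicate 2. That probe gave 1.14 without that array, and its call was lost without any 1 of the 4 treated arrays. The other HLA-C probe, used without the patch, gave 0.98 (limma with every probe on its own, adjusted p = 0.00173).

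Of the 16 cancer-testis antigens, genes normally restricted to germ cells, that were tested, 7 rose and 2 fell (8 and 2 adjusted over the list alone, camera, adjusted p = 0.315). VCX2 was at least 3.65-fold higher and CTAG1A, which encodes NY-ESO-1, at least 4.39-fold higher. Both have near-identical copies, and the CTAG1A probe lies in the dim patch. Of the 37 tumour-suppressor and silenced-in-cancer genes tested, 15 rose and 12 fell (16 and 13 adjusted over the list alone, camera, adjusted p = 0.775). NDRG4 rose 8.6-fold and SLIT2, an axon guidance ligand, by 2.36 ± 0.26 on the log2 scale. Of the 29 output genes of the MAPK and PI3K pathways tested, 7 rose and 14 fell (8 and 14 adjusted over the list alone, camera, adjusted p = 0.315). EGR1, an immediate-early transcription factor, fell by 1.49 ± 0.08, and LIF, a cytokine, was at least 2.8-fold lower. Of the 35 ER stress genes tested, 11 rose and 10 fell (12 and 10 adjusted over the list alone, camera, adjusted p = 0.87). CHAC1, a glutathione-degrading enzyme, fell by 2.29 ± 0.22. Single members of lists that did not pass also rose. MAP2, a neuronal microtubule protein, was at least 5.96-fold higher, LCP1, the leukocyte plastin, at least 2.2-fold higher and ICOSLG, the ICOS ligand, at least 2.93-fold higher. VGF, a neuropeptide precursor, rose by 1.93 ± 0.10, PDGFRB, a PDGF receptor, by 1.58 ± 0.19 and FADS1, a fatty acid desaturase, by 1.49 ± 0.18. With spike-in scaling SCG2 (0.51), RIGI (0.16), HLA-C (0.81), TAPBP (0.06), PDGFRB (0.52) and FADS1 (0.43) lost their calls. Unscaled, STING1 (0.54, adjusted p = 0.0609), RIGI (0.38, adjusted p = 0.143), HLA-C (1.03, adjusted p = 0.0629) and TAPBP (0.29, adjusted p = 0.305) did. With normexp background correction, whose offset shrinks changes, 24 of the 44 called genes named here changed by over 1.5 times less on the log2 scale, and 43 kept their call and direction. The 15 other lists, immune checkpoint and NK ligands, cytokines, silenced germline genes, MHC class II, endogenous retroviral genes, imprinted genes, neuronal genes, cholesterol and fatty acid synthesis, fatty acid oxidation, smooth muscle, epithelial, leukocyte, Schwann and melanocyte, fibroblast and endothelial and homeobox genes, had adjusted p between 0.169 and 0.991 in camera. Of these, the cytokine, neuronal and fatty acid oxidation lists had a median and a test pointing down but a mean above 0, and the endogenous retroviral and leukocyte lists a median and a mean above 0 but a test pointing down.

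**Figure D2:**
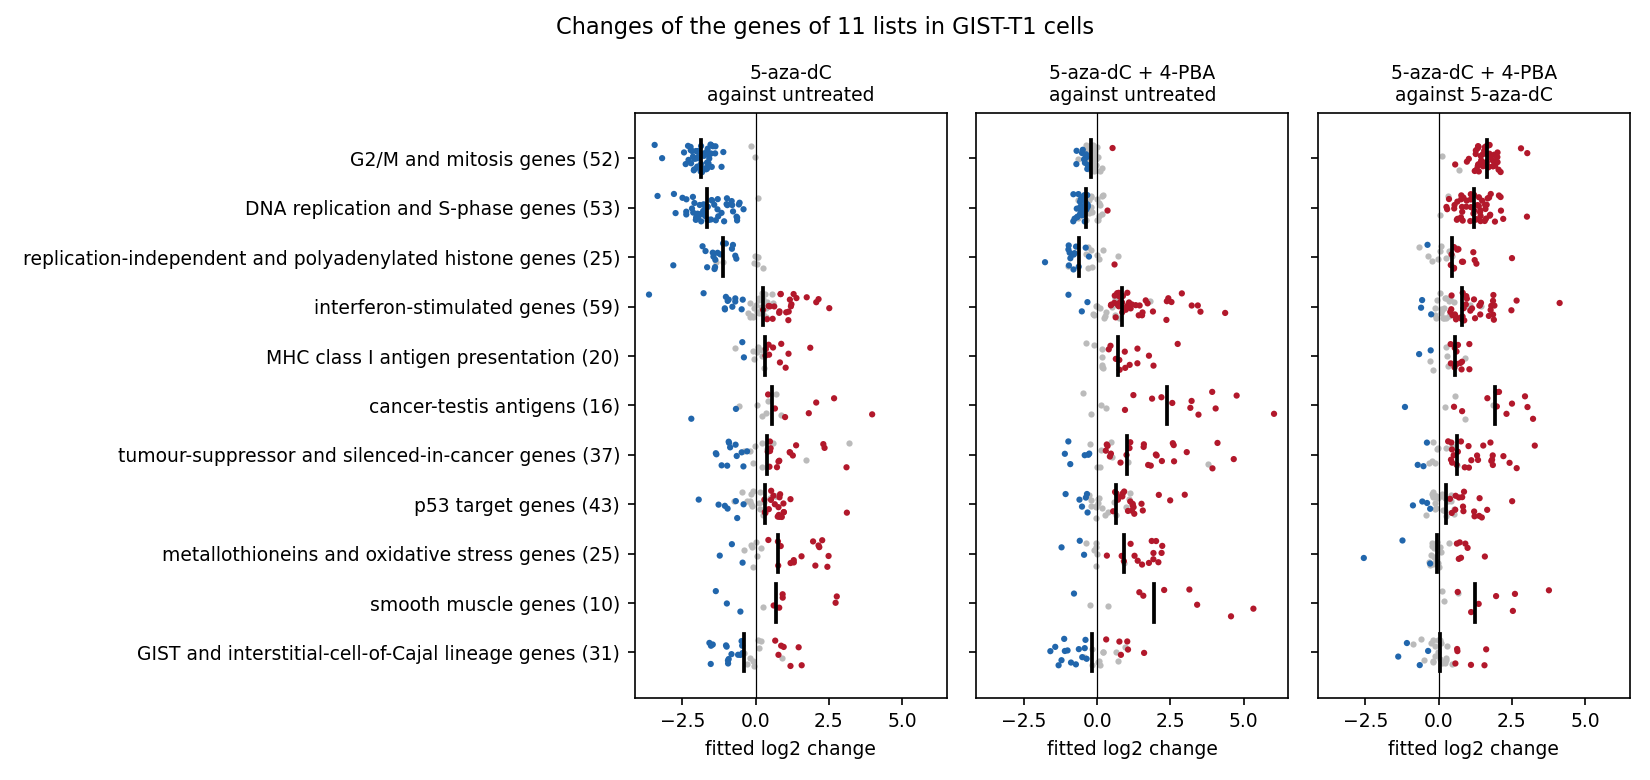
Fitted log2 change (horizontal axis) of every tested member of 11 of the 29 gene lists in the 3 comparisons, with 1 row per list and its number of tested members in brackets; red and blue points were called higher and lower, grey points were not called, black bars are medians, and vertical scatter is for display. The median of the G2/M and mitosis genes was -1.86 after 5-aza-dC, -0.22 after the combined treatment and 1.63 between the treatments.

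The second comparison set the combined treatment, 5-aza-dC followed by 4-PBA, against untreated cells, whose arrays stood in another row of the slide. CNN1, the smooth muscle protein calponin 1 (chromosome 19, 11661005 to 11661064 in hg19), rose the most of the named genes measured on every array, by 5.34 ± 0.07 (40.4-fold, adjusted p = 0.000227). ACTG2, the actin of gut smooth muscle, rose by 4.57 ± 0.10 (23.8-fold), IGFBP3, an insulin-like growth factor binding protein, by 4.67 ± 0.11 (25.4-fold), and ADAMTS8, a secreted metalloproteinase, by 4.25 ± 0.16. The largest falls were smaller: FAM163A fell by 2.59 ± 0.15, LETR1 by 2.32 ± 0.27, RASL11A by 2.27 ± 0.16, and MYCN, a MYC family transcription factor, by 1.99 ± 0.13. In all, 6002 genes changed, 3267 higher and 2735 lower. Of the 1640 that changed at least 2-fold, 1375 were higher and 265 lower. The share of called genes that were higher, 54.4%, was 43.5% with median centring, 39.3% with the percentile over all probes, 35.4% with spike-in scaling and 30.5% unscaled. Without replicate 1 of the combined treatment, 2601 genes were called, 1818 higher and 783 lower, and without replicate 2, 2685, 1834 higher and 851 lower. Without untreated replicate 2, 4017 were called, 2638 higher and 1379 lower. The share higher was then 69.9%, 68.3% and 65.7%. TMEM35A was at least 16.1-fold higher, CDC42EP1 at least 12.3-fold higher, GTSF1, a germ-cell protein of the piRNA pathway, at least 5.12-fold higher and C3orf70 at least 1.77-fold higher, each against untreated arrays not well above background (largest adjusted p = 0.000307). In this comparison probes nearer the 5' end of a gene stood -0.13 from those nearer the 3' end of the same gene in median log2 change (95% interval -0.144 to -0.0995, 1980 genes). This and the other 95% intervals given come from resampling genes, not arrays, so they hold no spread between arrays.

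Interferon-stimulated genes were higher, with a median change of 0.83, which was 0.46 with normexp and 0.52 unscaled. Of the 59 interferon-stimulated genes tested, 43 rose and 3 fell (44 and 3 adjusted over the list alone, camera, adjusted p = 4.95e-10, and adjusted p = 0.118 with an estimated correlation). ISG20, an antiviral exonuclease, was at least 5.13-fold higher (adjusted p = 0.000528), and IFI27 rose by 3.53 ± 0.21 (11.5-fold). Of the 20 genes of MHC class I antigen presentation tested, 13 rose and 0 fell (camera, adjusted p = 4.93e-05, and adjusted p = 0.162 with an estimated correlation). TAP1, the peptide transporter, rose by 1.93 ± 0.14. HLA-C was 2.75 ± 0.48 (adjusted p = 0.0128) on the probe in the dim patch, a call lost without replicate 1 or 2 of the combined treatment. The other HLA-C probe, used without the patch, gave 2.15 (limma with every probe on its own, adjusted p = 0.000529). Of the 13 immune checkpoint and NK ligands tested, 11 rose and 0 fell (11 and 1 adjusted over the list alone, camera, adjusted p = 0.000127, and adjusted p = 0.126 with an estimated correlation). TNFSF4, the OX40 ligand, rose by 3.65 ± 0.09 (12.5-fold). Of the 9 interferons, chemokines and cytokines tested, 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera, adjusted p = 0.0294, and adjusted p = 0.162 with an estimated correlation). IL32 rose by 3.89 ± 0.12. The array held 24 checkpoint and NK ligands and 41 of these cytokine genes, of which 13 and 9 passed the filter on dim probes. Those dim in untreated cells entered only by being bright after a treatment. Part of the rises of these lists, here and between the treatments, may thus follow from the filter. Of the 16 nucleic-acid sensors and adaptors tested, 4 rose and 0 fell (2 and 0 adjusted over the list alone, camera, adjusted p = 0.0932), and the list passed without untreated replicate 2 (adjusted p = 0.0135) and with every probe on its own (adjusted p = 0.00606). STING1 rose by 1.48 ± 0.07. RIGI was 0.90 ± 0.16 and lost its call with the mean of its probes (0.18, adjusted p = 0.418), unscaled (adjusted p = 0.0612) and without replicate 1 or 2 of the combined treatment (adjusted p = 0.0714 and 0.0765).

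Cancer-testis antigens were also higher, with a median of 2.38, or 1.18 with genes below background at their bound and 0.56 with normexp. On the array were 58 of them and 66 tumour-suppressor and silenced-in-cancer genes, of which 16 and 37 passed the filter on dim probes. Those dim in untreated cells entered only by being bright after a treatment, so part of these rises follows from the filter. Of the 16 cancer-testis antigens tested, 12 rose and 0 fell (12 and 1 adjusted over the list alone, camera, adjusted p = 0.000125, and adjusted p = 0.162 with an estimated correlation). VCX2 was at least 15.2-fold higher and PAGE2B at least 7.7-fold higher, and both belong to families of near-identical copies. Of the 37 tumour-suppressor and silenced-in-cancer genes tested, 23 rose and 6 fell (25 and 6 adjusted over the list alone, camera, adjusted p = 3.1e-05, and adjusted p = 0.118 with an estimated correlation). PHLDA2, an imprinted growth regulator, was at least 4.06-fold higher. Of the 26 imprinted genes tested, 11 rose and 2 fell (camera, adjusted p = 0.0331, and adjusted p = 0.162 with an estimated correlation). The imprinted median, 0.12, was -0.039 with spike-in scaling and -0.19 unscaled. Of the 8 germline genes silenced by promoter methylation tested, 3 rose and 1 fell (camera, adjusted p = 0.0932), and the list passed without untreated replicate 2 (adjusted p = 0.044), with every probe on its own, with the mean of each gene's probes, without the filter on dim probes and unscaled (adjusted p = 0.0375, 0.0436, 0.0183 and 0.00246). Of the 43 p53 target genes tested, 20 rose and 6 fell (21 and 6 adjusted over the list alone, camera, adjusted p = 0.000743, and adjusted p = 0.126 with an estimated correlation). GDF15 rose by 2.99 ± 0.08 and PHLDA3, an inhibitor of AKT, by 2.49 ± 0.13. Of the 25 metallothioneins and oxidative stress genes tested, 15 rose and 3 fell (16 and 4 adjusted over the list alone, camera, adjusted p = 0.000452, and adjusted p = 0.275 with an estimated correlation). MT2A rose by 2.22 ± 0.11. Of the 31 cholesterol and fatty acid synthesis genes tested, 13 rose and 1 fell (15 and 2 adjusted over the list alone, camera, adjusted p = 0.0336, and adjusted p = 0.162 with an estimated correlation). FADS1 rose by 1.48 ± 0.18, while the median of the list, 0.25, was -0.065 unscaled, where its call was lost (adjusted p = 0.106), as it was without the filter on dim probes (adjusted p = 0.168).

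Lists of markers of other cell types were higher in the combined group. Tested were 10 of 16 smooth muscle, 8 of 16 fibroblast and endothelial and 25 of 58 neuronal genes on the array. For leukocyte, epithelial, and Schwann and melanocyte genes it was 13 of 22, 10 of 24 and 4 of 16. A marker dim in the other groups entered only by being bright in the combined one. Part of these rises, here and between the treatments, thus follows from the filter. Of the 10 smooth muscle genes tested, 7 rose and 1 fell (camera, adjusted p = 0.000405, and adjusted p = 0.152 with an estimated correlation). Of the 8 fibroblast and endothelial genes tested, 8 rose and 0 fell (camera, adjusted p = 4.98e-05, and adjusted p = 0.126 with an estimated correlation). POSTN, periostin, rose by 3.20 ± 0.25. Of the 25 neuronal genes tested, 9 rose and 0 fell (camera, adjusted p = 0.00291, and adjusted p = 0.152 with an estimated correlation). MAP2 was at least 16.02-fold higher and UCHL1, a neuronal ubiquitin hydrolase, rose by 2.63 ± 0.21. Of the 13 leukocyte genes tested, 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera, adjusted p = 0.0158, and adjusted p = 0.162 with an estimated correlation). LCP1 was at least 3.46-fold higher. Of the 10 epithelial genes tested, 4 rose and 0 fell (7 and 1 adjusted over the list alone, camera, adjusted p = 0.0429, and adjusted p = 0.201 with an estimated correlation). KRT17, a keratin, was at least 6.83-fold higher. Of the 4 Schwann and melanocyte genes tested, 4 rose and 0 fell (camera, adjusted p = 0.0147, and adjusted p = 0.201 with an estimated correlation). NGFR, the low-affinity nerve growth factor receptor, was at least 4.18-fold higher. No list of this comparison passed camera with an estimated correlation. Correlation between genes does not by itself account for that. The p53 targets, with an estimate of -0.013, below the preset 0.01, lost their call too. Camera with an estimated correlation tests on the 3 residual degrees of freedom of the fit, and with a preset one it does not. That raises p-values even at low estimates. With a preset correlation, the epithelial and cholesterol lists lost their calls without replicate 1 of the combined treatment (adjusted p = 0.14 and 0.0556) and with normexp (adjusted p = 0.0633 and 0.0989). The imprinted list lost its call without untreated replicate 2 (adjusted p = 0.053), without replicate 2 of the combined treatment (adjusted p = 0.0534) with the mean of each gene's probes (adjusted p = 0.0596) and with every probe on its own (adjusted p = 0.0776). With only genes well above background on all arrays, the calls of the cancer-testis (adjusted p = 0.235), cytokine (adjusted p = 0.0705), leukocyte (adjusted p = 0.169), epithelial (adjusted p = 0.568) and imprinted lists (adjusted p = 0.249) were lost. The Schwann and melanocyte list had too few such genes to be tested there in any comparison.

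Genes of cell division were lower than in untreated cells, with medians of -0.22 for G2/M and mitosis and -0.39 for DNA replication. Of the 52 G2/M and mitosis genes tested, 1 rose and 12 fell (1 and 8 adjusted over the list alone, camera, adjusted p = 0.000139, and adjusted p = 0.152 with an estimated correlation). The number that fell depended on the scaling, with 11 unscaled, 18 with normexp, 19 with median centring, 24 with the percentile over all probes and 27 with spike-in scaling. MAD2L1, of the spindle checkpoint, fell by 0.71 ± 0.11, and SGO1, shugoshin, was -0.70 ± 0.10, a call lost without replicate 1 of the combined treatment. The other SGO1 probe gave -1.13 (limma with every probe on its own, adjusted p = 0.016). Of the 53 DNA replication and S-phase genes tested, 1 rose and 29 fell (camera, adjusted p = 3.01e-06, and adjusted p = 0.118 with an estimated correlation). In the same settings 28, 33, 36, 38 and 39 of the replication genes fell. POLA2, a subunit of DNA polymerase alpha, was -0.81 ± 0.13, a call lost without replicate 1 or 2 of the combined treatment (adjusted p = 0.0599 and 0.062). Of the 25 listed histone genes tested, 1 rose and 14 fell (camera, adjusted p = 0.000139, and adjusted p = 0.162 with an estimated correlation). H2AC6 was -0.98 ± 0.13, a call lost without replicate 1 of the combined treatment (adjusted p = 0.0522), and H4C8 was -1.78 ± 0.36, a call lost without untreated replicate 1 or 2 (adjusted p = 0.0591 and 0.0946). DNMT3B rose by 1.13 ± 0.14 (adjusted p = 0.0055) and HDAC5, a class II histone deacetylase, by 1.34 ± 0.08. DNMT1 (-0.37 ± 0.13), DNMT3A (0.16 ± 0.09), HDAC1 (0.16 ± 0.09) and HDAC2 (-0.10 ± 0.10) did not pass, and DNMT1 passed as lower in 6 other settings, among them without untreated replicate 1 (-0.53, adjusted p = 0.0312). Of the 31 genes of the GIST and interstitial-cell-of-Cajal lineage tested, 6 rose and 14 fell (camera, adjusted p = 0.1). That list passed as lower with the mean of each gene's probes (median -0.36, adjusted p = 0.0318) and without the filter on dim probes (median -0.023, adjusted p = 0.0026). KIT fell by 0.89 ± 0.08 (1.86-fold lower, adjusted p = 0.00277), and its other probes gave -1.12 and -0.16. NRP1, neuropilin 1, rose by 1.60 ± 0.08, or by 2.47 as the mean of its probes. CD34 was -1.60 ± 0.26 (adjusted p = 0.0105), a call lost without replicate 1 or 2 of the combined treatment. Its other probe gave -1.33 (limma with every probe on its own, adjusted p = 0.00289). PIM1, a kinase on the list of MAPK and PI3K outputs, rose by 3.09 ± 0.14. The 7 other lists, MAPK and PI3K output, MHC class II, endogenous retroviral, ER stress, fatty acid oxidation, homeobox and methylation and deacetylation machinery, had adjusted p between 0.0989 and 0.838 in camera. The homeobox list passed with normexp (adjusted p = 0.0403), and it and the methylation machinery passed without the filter on dim probes (adjusted p = 0.0316 and 0.0156). Without the filter on dim probes, RIGI, HLA-C, MAD2L1, SGO1, POLA2, CD34 and H4C8 lost their calls (adjusted p between 0.0544 and 0.0796). With normexp, the medians of 14 of the 19 lists that passed were over 1.5 times smaller, and 17 still passed. With normexp, 26 of the 44 called genes named here changed by over 1.5 times less on the log2 scale, and 44 kept their call and direction.

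**Figure D3:**
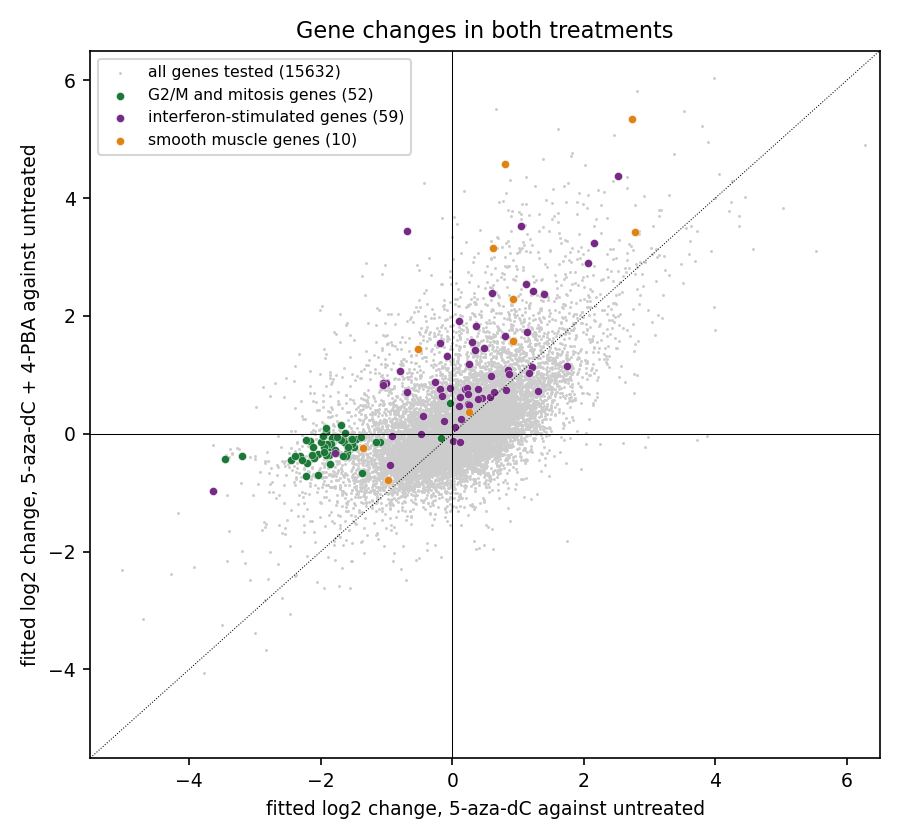
Fitted log2 change of each of the 15632 tested genes after 5-aza-dC (horizontal axis) and after 5-aza-dC followed by 4-PBA (vertical axis), both against untreated cells, with the dotted line at equal changes and 3 gene lists in colour. The G2/M and mitosis genes lie to the left, at a median of -1.86 after 5-aza-dC, and the interferon-stimulated and smooth muscle genes lie higher, at medians of 0.83 and 1.93 after the combined treatment.

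Many genes were called after both treatments. GDF15, STING1, FADS1, MAP2, LCP1 and VCX2 were called higher in both comparisons and KIT lower, although the call of STING1 after 5-aza-dC was lost unscaled and that of FADS1 with spike-in scaling. In all, 3523 genes were called in the same direction in both, 2020 higher and 1503 lower, and 449 in opposite directions. Independent lists of these sizes would share 879 higher and 599 lower genes, and 100 simulations of unchanged groups against the same untreated arrays shared at most 1. Unchanged groups give almost no calls, so that last count is near 0 by construction and is no measure of a shared effect. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.57, against 0.50 on average in the simulations. Their covariance was 0.355, against 0.0239. The 2 untreated arrays serve both comparisons and are too few to split, so part of the excess may come from the shared controls. The split of the shared genes depended on the scaling: 426 were higher and 4362 lower with spike-in scaling, and 365 and 2789 unscaled. Without replicate 1 of the combined treatment 1717 genes were shared, 1198 higher and 519 lower, and without replicate 2 1763, 1210 higher and 553 lower. Without untreated replicate 2 they were 2574, 1717 higher and 857 lower, and without 5-aza-dC replicate 1 2539, 1553 higher and 986 lower.

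The third comparison set the combined treatment against 5-aza-dC alone. The groups differ in 4-PBA, in the row of the slide, and possibly in 48 h of culture, so its changes cannot be ascribed to 4-PBA alone. Probes nearer the 5' end stood -0.07 from those nearer the 3' end of the same gene in median log2 change (95% interval over genes -0.0915 to -0.0513, 1980 genes), so a difference in RNA quality between the groups is not excluded. Cell division genes were higher in the combined group, with medians of 1.63 for G2/M and mitosis and 1.21 for DNA replication. Of the 52 G2/M and mitosis genes tested, 50 rose and 0 fell (51 and 0 adjusted over the list alone, camera, adjusted p = 8.88e-24, and adjusted p = 0.0483 with an estimated correlation). Of the 53 DNA replication and S-phase genes tested, 51 rose and 0 fell (camera, adjusted p = 1.08e-20, and adjusted p = 0.0483 with an estimated correlation). RRM2 rose by 3.01 ± 0.13 (8.08-fold), TOP2A was at least 6.88-fold higher, and CENPA rose by 2.81 ± 0.17, with 1 of the 2 5-aza-dC arrays well above background. Gene signal against the spike-ins was also higher than on the 5-aza-dC arrays, and spike-in scaling moved the median change of all genes to 0.86 and the share of called genes that were higher from 48.7% to 98.8%. Unscaled arrays gave 0.49 and 96.0%. Among named genes measured on every array of both groups, the largest rises were those of BST2, the interferon-induced restriction factor tetherin (chromosome 19, 17513748 to 17513807 in hg19), by 4.13 ± 0.15 (17.5-fold), TSPO, of the outer mitochondrial membrane, by 3.88 ± 0.10, ACTG2 by 3.76 ± 0.10, and COL9A3, a collagen chain, by 3.47 ± 0.10. The largest falls were those of HMOX1, heme oxygenase 1 (chromosome 22, 35790122 to 35790181 in hg19), by 2.56 ± 0.08 (5.89-fold lower), MMP3, stromelysin 1, by 2.42 ± 0.30, EFCC1 by 2.19 ± 0.08, and MMP1 by 1.83 ± 0.07. In all, 6615 genes changed, 3221 higher and 3394 lower, and of the 1839 that changed at least 2-fold, 1393 were higher. Of the 4207 genes higher after 5-aza-dC alone, 2122 were lower in the combined group than after 5-aza-dC and 447 higher still. Of the 3421 lower after 5-aza-dC alone, 1844 were higher in the combined group and 83 lower still. The same 5-aza-dC arrays stand on both sides of these counts, so their chance values add to the number that turned back. Without 5-aza-dC replicate 1, 4171 genes were called, 2313 higher and 1858 lower, and without replicate 2, 4303, 2512 higher and 1791 lower. Without replicate 1 of the combined treatment they were 3098, 1802 higher and 1296 lower, and without replicate 2 3515, 1945 higher and 1570 lower.

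Of the 59 interferon-stimulated genes tested, 35 rose and 3 fell (37 and 3 adjusted over the list alone, camera, adjusted p = 1.95e-08, and adjusted p = 0.0915 with an estimated correlation). USP18 was at least 1.31-fold higher (adjusted p = 0.000507). Of the 20 genes of MHC class I antigen presentation tested, 12 rose and 2 fell (camera, adjusted p = 0.0069, and adjusted p = 0.307 with an estimated correlation). TAP1 rose by 1.05 ± 0.14, and PSMB9, an immunoproteasome subunit, was 1.05 ± 0.16, a call lost without replicate 2 of the combined treatment (adjusted p = 0.0535). Of the 13 immune checkpoint and NK ligands tested, 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera, adjusted p = 0.0114, and adjusted p = 0.178 with an estimated correlation). TNFSF4 rose by 2.12 ± 0.09. SERPINB9, an inhibitor of granzyme B, was at least 4.07-fold higher, GALNT16 at least 2.97-fold higher, FOLR1, a folate receptor, at least 2.32-fold higher and CDC42EP1 at least 6.37-fold higher, each against 5-aza-dC arrays not well above background (largest adjusted p = 0.000496). Of the 9 interferons, chemokines and cytokines tested, 5 rose and 0 fell (camera, adjusted p = 0.0131, and adjusted p = 0.183 with an estimated correlation). Of the 29 output genes of the MAPK and PI3K pathways tested, 11 rose and 0 fell (camera, adjusted p = 0.0121, and adjusted p = 0.178 with an estimated correlation). LIF, on both of these lists, was at least 4.85-fold higher. Of the 16 cancer-testis antigens tested, 11 rose and 1 fell (12 and 1 adjusted over the list alone, camera, adjusted p = 0.000171, and adjusted p = 0.2 with an estimated correlation). MAGEA9, which has a near-identical copy, was at least 1.87-fold higher. Of the 37 tumour-suppressor and silenced-in-cancer genes tested, 25 rose and 3 fell (25 and 4 adjusted over the list alone, camera, adjusted p = 1.91e-05, and adjusted p = 0.0915 with an estimated correlation). IGFBP3 rose by 3.28 ± 0.11. Of the 43 p53 target genes tested, 16 rose and 4 fell (camera, adjusted p = 0.0193, and adjusted p = 0.178 with an estimated correlation). PTPRU, a receptor tyrosine phosphatase, rose by 2.51 ± 0.08 and PHLDA3 by 1.66 ± 0.13.

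Of the 10 smooth muscle genes tested, 7 rose and 0 fell (camera, adjusted p = 5.76e-05, and adjusted p = 0.178 with an estimated correlation). Of the 8 fibroblast and endothelial genes tested, 7 rose and 0 fell (7 and 1 adjusted over the list alone, camera, adjusted p = 0.00214, and adjusted p = 0.178 with an estimated correlation). POSTN rose by 2.00 ± 0.25. Of the 25 neuronal genes tested, 14 rose and 3 fell (14 and 4 adjusted over the list alone, camera, adjusted p = 0.0262, and adjusted p = 0.191 with an estimated correlation). UCHL1 rose by 1.85 ± 0.21. Of the 4 Schwann and melanocyte genes tested, 3 rose and 0 fell (4 and 0 adjusted over the list alone, camera, adjusted p = 0.0114, and adjusted p = 0.208 with an estimated correlation). PMEL, a melanosome protein, was at least 5.87-fold higher. Of the 25 listed histone genes tested, 13 rose and 1 fell (14 and 1 adjusted over the list alone, camera, adjusted p = 0.00214, and adjusted p = 0.2 with an estimated correlation). H2AJ rose by 1.29 ± 0.10 and H2BC7 was at least 1.16-fold higher. Of the 31 cholesterol and fatty acid synthesis genes tested, 11 rose and 3 fell (camera, adjusted p = 0.0273, and adjusted p = 0.183 with an estimated correlation). EBP, a sterol isomerase, rose by 1.41 ± 0.11. The 13 lists that did not pass were silenced germline genes, nucleic-acid sensors, MHC class II, endogenous retroviral genes, lineage, imprinted genes, methylation and deacetylation machinery, ER stress, fatty acid oxidation, metallothioneins and oxidative stress, epithelial, leukocyte and homeobox (camera, adjusted p between 0.0823 and 0.926). Of these, the leukocyte list passed with quantile normalization (adjusted p = 0.0211), with normexp (adjusted p = 0.0381), with every probe on its own (adjusted p = 0.0464) and without the filter on dim probes (adjusted p = 0.0242, with a median of -0.10). The epithelial list passed with the mean of each gene's probes (adjusted p = 0.0489), the ER stress list with every probe on its own (adjusted p = 0.0179) and without the filter (adjusted p = 0.000127), and the imprinted list and the methylation machinery without the filter (adjusted p = 0.013 and 0.0432). In the main setting, the endogenous retroviral list had a median and a test pointing up but a mean under 0, the methylation machinery a median and a test pointing down but a mean above 0, and the metallothioneins a mean and a test pointing up but a median under 0. Of the members of these lists, CORO1A, coronin 1A of leukocytes, was at least 2.55-fold higher, CHAC1 rose by 1.95 ± 0.22, TXNIP, a thioredoxin inhibitor, fell by 1.24 ± 0.08, THY1 rose by 1.62 ± 0.08 and PLAT, tissue plasminogen activator, by 1.56 ± 0.07. KIT was 0.57 ± 0.08 (adjusted p = 0.00751), but its other probes gave -0.11 and 1.01, and its call was lost without replicate 1 of the combined treatment (adjusted p = 0.0545). DNMT3B rose by 1.26 ± 0.14 (adjusted p = 0.00368). DNMT1 was 0.80 ± 0.13 (adjusted p = 0.0103), a call lost without 5-aza-dC replicate 1 (adjusted p = 0.0534) and without replicate 1 or 2 of the combined treatment (adjusted p = 0.0588 and 0.0635). Without the filter on dim probes KIT and DNMT1 both had an adjusted p of 0.0546. DNMT3A (-0.19 ± 0.09), HDAC1 (0.24 ± 0.09) and HDAC2 (0.02 ± 0.10) did not pass, and HDAC1 passed in 5 other settings, among them without untreated replicate 1 (adjusted p = 0.0496). The cholesterol list lost its call unscaled (adjusted p = 0.085). The neuronal list lost its call without untreated replicate 1 (adjusted p = 0.0672) and the cholesterol list without 5-aza-dC replicate 2 (adjusted p = 0.0723) and with normexp (adjusted p = 0.0855). With only genes well above background on all arrays the cancer-testis and neuronal lists lost theirs (adjusted p = 0.334 and 0.0743), and without the filter on dim probes the cytokine, neuronal and Schwann lists did, with medians of -0.49, -0.51 and -0.23. With spike-in scaling only the lists of G2/M and mitosis, DNA replication, interferon-stimulated, smooth muscle, and tumour-suppressor and silenced-in-cancer genes passed. With normexp, the medians of 8 of the 16 lists that passed were over 1.5 times smaller, that of the interferon-stimulated genes at 0.36 against 0.79, and 15 still passed. With normexp, 17 of the 38 called genes named here changed by over 1.5 times less on the log2 scale, and 38 kept their call and direction.

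**Figure D4:**
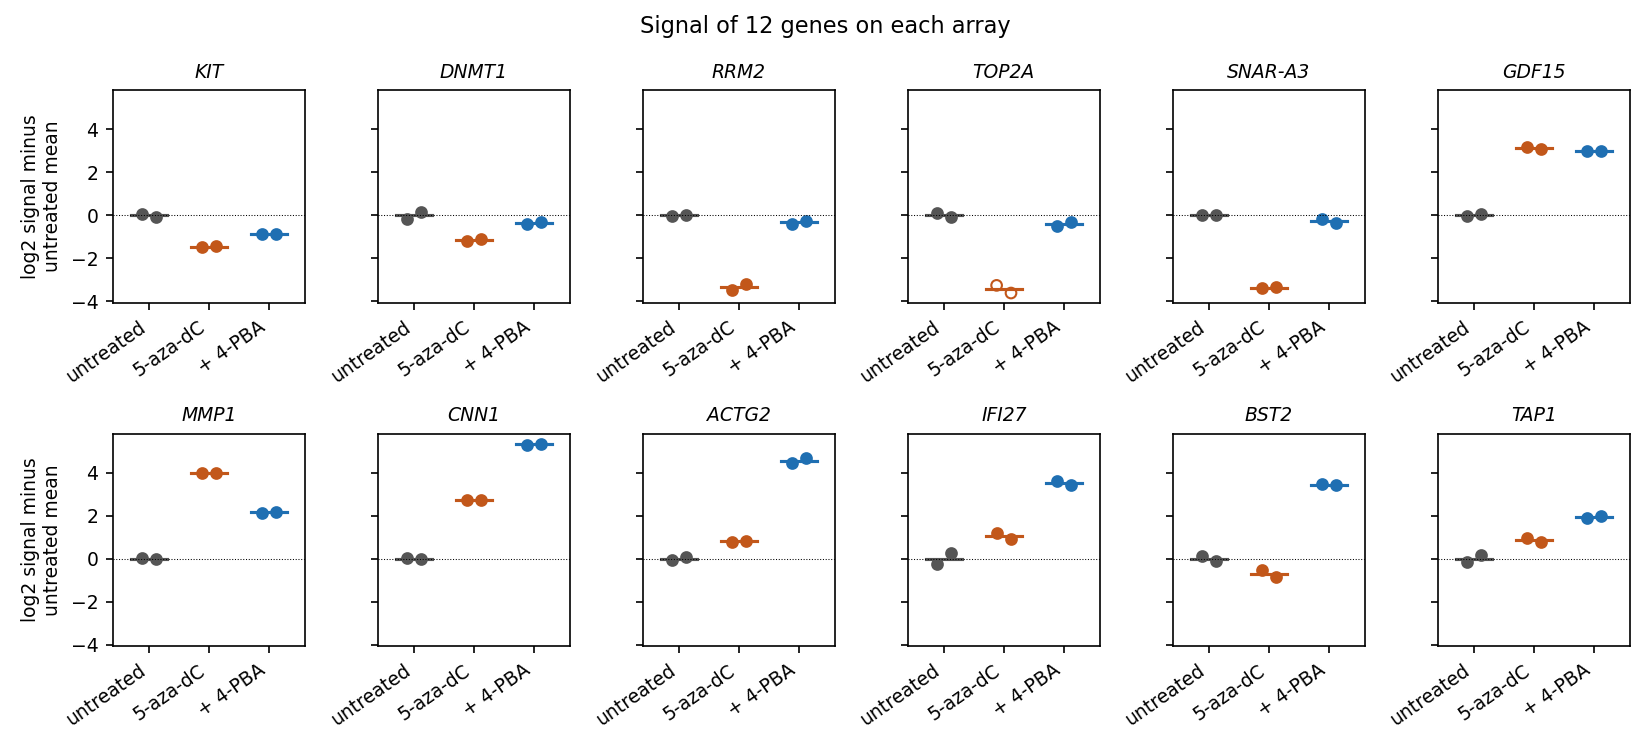
Log2 signal of 12 of the named genes on each of the 6 arrays, minus the mean of the untreated arrays (vertical axis), by group (horizontal axis); points are arrays, bars are group means of n = 2, and hollow points were not well above background. CNN1 stood 5.34 above the untreated mean after the combined treatment, and RRM2 stood at -3.35 after 5-aza-dC alone.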

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

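The tests of random spike-in error and of fewer transcripts were chosen after the result was seen. Spike-in RNA, which no comparison uses, was brighter against the genes on the 5-aza-dC arrays than on the untreated arrays, by 1.06 on the log2 scale. Gene signal minus spike-in signal was -1.95 and -1.97 on the untreated arrays, -3.01 and -3.03 after 5-aza-dC, and -2.07 and -2.18 after the combined treatment.

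Random error in the amount of spike-in stays open: the arrays of a group differed by at most 0.102, but the labels leave open whether they are repeat hybridisations of 1 RNA, which would share 1 addition of spike-in and agree whatever its error. More degraded RNA in the 5-aza-dC samples stays open: probes nearer the 5' end stood -0.0338 from those nearer the 3' end in median log2 change (95% interval -0.0656 to -0.00914). Against the bounds written before it was seen, it lies far above -0.2, which degradation as the cause would give, and above -0.05, but its interval crosses -0.05, and the combined treatment, whose spike-in shift was small, gave -0.126. That interval was resampled over genes and holds no spread between arrays. Fewer messenger transcripts per mass of total RNA stay open: with spike-in scaling 91.4% of tested genes were lower after 5-aza-dC, but that restates the shift and supports no cause, and a spike-in amount that differed between groups, by error or otherwise, would give the same, so these cannot be told apart. An effect of 5-aza-dC itself on the amount of messenger RNA stays open and was not tested.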

How the results depend on the processing

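The 75th percentile over all non-control probes, spike-in scaling, no scaling and leaving out the dim patch were chosen after the data were seen. Over the alternatives, 1629 of 1737 list results and 2871 of 2948 results for named genes kept their direction and their side of the threshold, 71 and 56 fell short of it, 35 and 18 newly passed, and 2 and 3 turned. These totals are no measure of robustness. They count lists that never passed, and settings that could change little, such as the series table's values, which kept all 87 list and 136 gene results. With an estimated correlation alone, 35 list results fell short. Without the filter on dim probes, 13206 genes were called for 5-aza-dC (7628 with it), 2019 for the combined treatment (6002), 2667 between the treatments (6615) and 1364 in both (3523), with 9 lists for 5-aza-dC (4). There camera's direction turned for 2 lists that now passed, while their medians kept their sign: the cholesterol list after 5-aza-dC, lower than other genes with a median of 0.071 (0.11 with the filter), and the methylation machinery between the treatments, higher than other genes with a median of -0.059 (-0.019). The surrogate values of dim probes entered those tests. After scaling, the lowest signal among probes well above background was -4.92 and -4.80 on the 5-aza-dC arrays. It was -6.14 and -5.66 on the untreated arrays and -5.49 and -5.60 on the combined ones. Of the 13206 genes called for 5-aza-dC, 10650 were higher. Dim genes thus tended to lie higher on the 5-aza-dC arrays, and a list lower than other genes there need not have fallen. Other causes were not tested. A 2-fold minimum gave 2444, 1640 and 1839 genes and 757 in both, through the stricter threshold. Spike-in scaling gave 12873 genes for 5-aza-dC, 500 higher and 12373 lower, and 12614 between the treatments, 12465 higher and 149 lower, with 7 and 5 lists against 4 and 16. That scaling moves all genes of an array together, which by construction turns the calls to 1 side, while the cause of the changed list calls was not tested. DNMT3A, at 0.34 after 5-aza-dC and -0.19 between the treatments, turned to -0.71 after 5-aza-dC and 0.71 between the treatments with spike-in scaling, and to -0.49 after 5-aza-dC unscaled. With an estimated correlation 2, 0 and 2 lists passed, against 4, 19 and 16. Lists with estimates below the preset 0.01 were among those lost, so correlation between genes does not by itself account for the losses. With an estimate, camera also tests on only the 3 residual degrees of freedom of the fit, which raises p-values. Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave 5663 to 6846 genes for 5-aza-dC, 2601 to 5372 for the combined treatment, 3098 to 7036 between the treatments and 1717 to 3367 in both. Without replicate 1 or 2 of the combined treatment the counts were 2601 and 2685 for the combined treatment, 3098 and 3515 between the treatments and 1717 and 1763 in both. Without replicate 1 or 2 of 5-aza-dC they were 4171 and 4303 between the treatments. Without untreated replicate 2 the combined treatment had 1379 lower genes, against 2735. A group then has 1 array, and the cause beyond that was not tested. Without the dim patch the counts for the 3 comparisons were 7802, 6152 and 6852. Deviations of same-numbered arrays correlated at 0.0303, 0.00782 and 0.0437, so the numbers were not taken to pair samples. A replicate block gave 7009, 5022 and 5782 genes and 2959 in both, and moved no list over the threshold and 1 named gene, DNMT3A after 5-aza-dC. The slide as a block was not run, since there is 1 slide. Signal over background limits what could be tested: 20971 genes were too dim.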

Other observations

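The gene families and the dim patch were picked after the data were examined, as were the tests of scaling and of an exchanged array for the cell division genes and of matched lists for the small RNAs. Of 20 families read from gene symbols, 7, 11 and 8 passed camera in the 3 comparisons, and they are given as values, counted over all genes tested. Only genes that passed the filter on dim probes were counted, so members dim in untreated cells entered only by being bright after a treatment. Part of the rises of families with silent members may follow from that. After the combined treatment 23 of 82 cytosolic ribosomal proteins fell and 1 rose (camera, adjusted p = 5.15e-05). There 61 of 194 solute carriers rose and 23 fell (adjusted p = 0.00803), 5 of 7 laminins rose and 0 fell (adjusted p = 0.0151), and 1 of 8 SNAR RNAs fell (adjusted p = 0.0337). Between the treatments 32 of 82 cytosolic ribosomal proteins fell and 4 rose (adjusted p = 0.00126). After 5-aza-dC 6 of 10 matrix metalloproteinases rose (camera, adjusted p = 0.0191), with a median of 1.06, which was 0.0019 with spike-in scaling, and 7 of 10 rose after the combined treatment (adjusted p = 0.00099). Between the treatments 5 fell and 1 rose (adjusted p = 0.192), with a median of -0.35 that was 0.54 with spike-in scaling and 0.17 unscaled. Of the collagens, 10 rose and 10 fell after 5-aza-dC (adjusted p = 0.798). After the combined treatment 19 of 25 collagens rose (adjusted p = 2.72e-06), with a median of 1.17, and 16 of 25 rose between the treatments (adjusted p = 1.19e-05). In the combined group 8 of 11 serpins (adjusted p = 0.000365) and 5 of 6 S100 proteins (adjusted p = 0.00099) rose too, as did 7 of 11 and 4 of 6 between the treatments (adjusted p = 0.0204 and 0.00886), and neither family passed after 5-aza-dC (adjusted p = 0.68 and 0.696). In the same group 16 of 22 cytosolic aminoacyl-tRNA synthetases fell (median -0.53, adjusted p = 2.72e-06), and 30 of 77 mitochondrial ribosomal proteins fell (median -0.27, adjusted p = 1.73e-07). Both families were also lower after 5-aza-dC, where 11 of 22 (adjusted p = 0.00231) and 23 of 77 fell (adjusted p = 0.00529), and neither passed between the treatments (adjusted p = 0.222 and 0.0887). After 5-aza-dC 8 of 16 tubulins (adjusted p = 0.00358) and 16 of 46 proteasome subunits (adjusted p = 0.000468) fell, and 11 of 16 tubulins rose between the treatments (adjusted p = 1.19e-05). After the combined treatment 10 of 46 proteasome subunits fell (adjusted p = 0.00278), and the tubulins did not pass (adjusted p = 0.077). Of 406 zinc-finger (ZNF) genes, 117 fell and 34 rose between the treatments (adjusted p = 0.00449). Of the SNAR RNAs, which are near-identical copies, 7 of 8 fell after 5-aza-dC (median -3.31, adjusted p = 1.69e-05) and 7 of 8 rose between the treatments (median 3.01). None of these families passed camera with an estimated correlation (lowest adjusted p = 0.0934 over all 20 families and 3 comparisons). That includes the mitochondrial ribosomal proteins, whose estimate, -0.00097, lay below the preset 0.01.

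The fall of cell division genes after 5-aza-dC was set against technical explanations. The scaling of the arrays is argued against, since the median of the G2/M list less that of all genes was at most -1.45 over 8 scalings, although only normexp and quantile normalization could have changed it. Loss of dim signal on the weaker 5-aza-dC arrays is argued against by matched random lists, 0 of 10000 of which had a median as low as -1.86 (lowest -0.40). An exchanged array is argued against, since 51 of 52 G2/M genes were lower on both 5-aza-dC arrays than on all 4 others, as were 3399 of 15632 genes in all, and chance gives 6.67%. A lower share of dividing cells at harvest may account for the fall, as a hypothesis that no value here tests, and a difference in culture density or harvest time between groups stays open.

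Small nucleolar and Cajal body RNAs were lower after 5-aza-dC: 100 of 187 fell (median -0.73; camera, adjusted p = 3.69e-11, and adjusted p = 0.313 with an estimated correlation), and 94 of 187 rose between the treatments (median 0.77). Loss of dim signal is argued against, since 0 of 10000 matched lists had a median as low (lowest -0.0995). Loss of short RNA by size stays open: box C/D RNAs, the shorter class, stood 0.228 above box H/ACA RNAs in median log2 change, with a 95% interval of -0.0462 to 0.648 that includes 0. Lower transcription of the host genes stays open too, with a median change of 0.0656 (95% interval -0.325 to 0.292) over 17 host genes. Both intervals were resampled over genes and hold no spread between arrays. Whether a biological effect of 5-aza-dC on these RNAs is the cause was not tested.

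Untreated replicate 2 had a dim patch at rows 170 to 229 and columns 72 to 95, covering 13 of 810 blocks of spots, against 0 on the other arrays. Its spots had a median of -1.81 on the log2 scale to the other arrays, and 42.9% differed from them by over 2, against 1.02% elsewhere. Blocks were put in the patch where a share over 0.15 of their spots differed by over 2, so that contrast follows from the choice. It held 294 tested genes, 89 of them called after 5-aza-dC, among them HLA-C and CTAG1A. The SD of the difference between the untreated arrays was 0.453 with it and 0.334 without it.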
